A study of Mus musculus with 12 samples.

How the data were processed

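Livers of male C57BL/6 offspring were taken at 12 weeks of age, and total RNA was made into TruSeq libraries and sequenced, per the labels' protocols. The labels list 12 samples, 3 in each of 4 groups of maternal and offspring diet, and the table of the series used here has 11 columns, of which 2 are CO libraries. The column names gave the group of each library but not which labelled sample it was, so libraries carry only a group and a number that pairs nothing. Which offspring shared a litter is not given in the sources used here, and p-values of single genes measure the spread between these libraries.

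The values the authors deposited are a signal, estimated gene counts divided by 1 factor per library, as read from the values themselves. Each column came from 1 alignment file and genes carry Ensembl identifiers, per the file headers. The file calls them CPM, but the values of a library summed to between 929699 in OO.0 and 1099404 in OO.1 and differed between libraries. Within each library between 95.73% and 97.34% of values were whole multiples of the value of 1 read, with a tolerance of 0.01, and the reads recovered that way had scaling factors that matched edgeR's TMM factors (both 0.910 in OO.1, the lowest, and 1.08 in OO.0, the highest). Alignment used Bowtie 1.2.3 and the mm8 build, per the submitters' processing notes. The read counter, the gene annotation, the strand setting and the scaling method are not given in the sources used here. How the counter divided reads between near-identical genes is likewise unknown, so values in the Serpina1, Mup, C4, Gbp, Cyp, Saa and Gst families are uncertain.

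The recovered depth was 3976158 (OO.1) to 27837609 (OO.0) reads per library. The value of 1 read ran from 0.0334 to 0.276, so that a floor of 3 reads lay between 0.1 and 0.829, which covers counting error only. Gene symbols were taken from a table of Ensembl identifiers and symbols for 11965 of 12086 genes, and 121 had none. An annotation of the build used for alignment was not used here, so no coordinates are given.

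The test was limma's moderated test with an intensity trend on log2(value + 0.5), fitted to all 11 libraries with 1 mean per group, so that groups share 1 estimate of the spread (7 residual and 4.66 prior degrees of freedom). Fold changes are on that log2 scale and understate changes of low genes. A gene had to reach a value of 1 in at least 3 libraries, which all 12086 genes did. The 7 comparisons were CO with CC, OO with OC, OC with CC, OO with CO, the average offspring diet effect, the average maternal diet effect and their interaction, each with Benjamini-Hochberg adjustment at 0.05. The design assumed CPM and 12 samples, and the test on the log scale was kept for the unit and the 11 libraries found.

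Gene lists for pathways and cell types, 32 in all, were fixed with the comparisons, the rule for named genes and most alternatives before the data were examined. Limma's camera with a preset correlation of 0.01 tested 31 of them, leaving out the lymphocyte list with 2 measured members, and camera with an estimated correlation and fry were run beside it. Camera sets the members of a list against all other genes, and the preset correlation treats members as nearly independent. Its p-values with that setting thus rest mainly on the spread between genes, not between libraries. With an estimated correlation, which allows for members that vary together, 0 lists were called in any comparison. Interferon-stimulated and skeletal muscle lists were written after the data were examined, and their results are not independent evidence. The genes named per comparison were the 10 with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 5 in the higher group and no overlap between groups (for averages, the same sign in both simple contrasts). Symbols of the form Gm plus digits or ending in Rik and unnamed identifiers were left out. Where fewer than 5 passed, the 5 with the smallest unadjusted p in each direction were named as missing the threshold. From each list up to 4 members with the smallest p served as examples. Some genes that this rule takes are not reported here. Pnlip, Acta1, Saa1, Saa2, Lars2, Gm15564, mt-Rnr1, Serpina1c, Gm8893 and Gm24105 were named after their values were seen.

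Alternatives were edgeR's quasi-likelihood test, DESeq2 and limma's voom on the recovered reads rounded to whole numbers, pseudocounts of 0.1 and 2, median-of-ratios and quantile scaling, a minimum value of 5 (10238 genes), a robust variance, sample weights, only the 2 groups compared, other thresholds and leaving out each library. Leaving out a CO library leaves 1 in that group, which is then assumed to vary like the libraries of the other groups. After the data were examined, fits without the 6 genes listed at 0 in a whole group, without the libraries with the most pancreas transcripts (OC.0 and CO.1) and without those with high acute phase transcripts (OC.1 and CO.1) were added. CC.1, in which pancreas transcripts made up 0.0971% of values, stayed in all of these fits, so they do not remove every library with pancreas transcripts. Limma's fit was tested on simulated data with the means and depths of these libraries for 12086 genes, with 100 genes changed at each size. It recovered 51%, 63% and 78% of changes of 1 on the log2 scale for CO with CC, OO with OC and the offspring average, and 95%, 90% and 95% of changes of 2. False calls were 10 of 156, 7 of 160 and 8 of 181. The simulated genes varied independently of one another and no simulated library stood apart, so these rates may not hold for the real libraries. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.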

Results

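Liver RNA was measured by RNA sequencing in male C57BL/6 mouse offspring killed at postnatal day 84 (12 weeks), fasted per the labels. The dams ate either a standard chow (7% simple carbohydrate, 3% lipid) or an obesogenic diet (10% simple carbohydrate and 20% lipid, with sweetened condensed milk of 55% simple carbohydrate, 8% lipid and 8% protein), and the offspring ate either diet from weaning at day 21. The 4 groups are named by the diet of the dam and then of the offspring, with C for control and O for obesogenic. The labels list 3 animals in each group, and the table used here held 11 libraries: CC, OC and OO with 3 libraries each and CO with 2. Libraries are called CC.0 to CC.2, CO.0 and CO.1, OC.0 to OC.2 and OO.0 to OO.2. The depth recovered from the values was lowest in OO.1 (3976158 reads) and, apart from OO.0 (27837609), highest in OC.0 (7969056). Values below are scaled counts, close to CPM, for 12086 genes.

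Several libraries stood apart from the others of their group. Exocrine pancreas transcripts were high in OC.0 and CO.1: Pnlip, pancreatic lipase, stood at 1111 in OC.0, 515.6 in CO.1 and 161.9 in CC.1, against 0.138 to 20.46 in the other 8 libraries. The acute phase transcripts Saa1 and Saa2, serum amyloids made by the liver in inflammation, stood at 5045 and 7410 in CO.1 and at 3415 and 4025 in OC.1, and Saa1 averaged 27.7 ± 7.58 (SD, n = 3) in CC. Skeletal muscle transcripts varied within groups, with Acta1 at 37.1 in OO.0 and 37.4 in CC.0 and at 0.277 in OO.1. Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 12.92% of all values in OO.1 (142071).

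Further, 6 genes were listed at 0 in every library of at least 1 group while being present in every library of the rest. The mitochondrial 16S rRNA mt-Rnr2 lay between 43306 and 51009 in the CC and OC libraries and was listed at 0 in all CO and OO libraries. Mup17, a major urinary protein gene with near-identical copies, lay between 106.8 and 1416 in CC and OC and was listed at 0 in CO and OO. In OO alone, Serpina1b, Serpina1d, Gm8893 and Gm24105 were listed at 0, against 2082 to 2679, 876 to 1434, 6.66 to 20.8 and 56.5 to 97.0 in the other groups. The companion 12S rRNA mt-Rnr1 was present in all libraries, at 6812 ± 322 (SD, n = 2) in CO, and so was Serpina1c, at 1288 ± 43.0 (SD, n = 3) in OO. An exact 0 in such abundant genes can be a failed estimate, so these genes are counted apart and given no fold change.

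**Figure D1:**
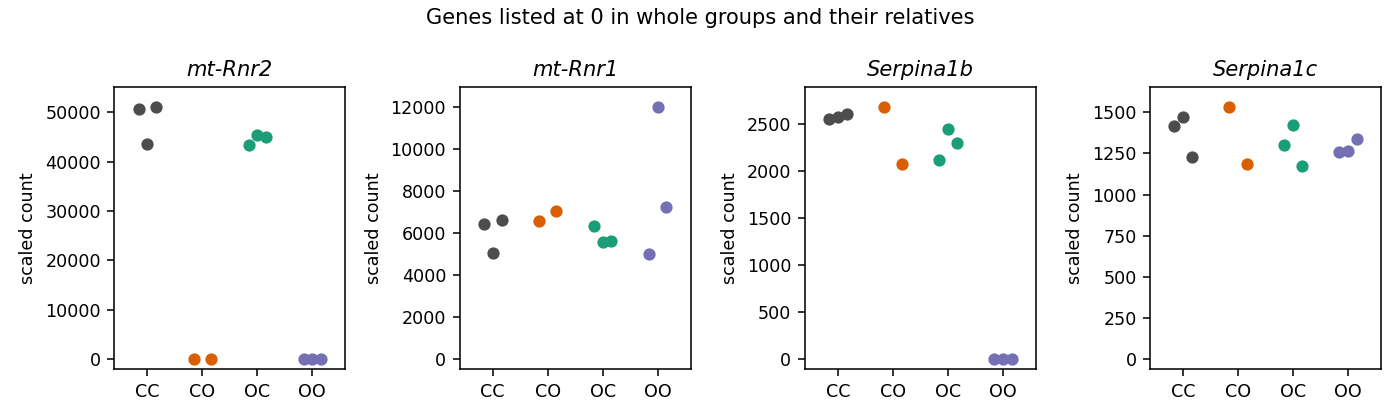
Scaled counts of mt-Rnr2, mt-Rnr1, Serpina1b and Serpina1c in each library (points), by group on the x axis. mt-Rnr2 is at 0 in all 5 CO and OO libraries and Serpina1b in all 3 OO libraries, while mt-Rnr1 and Serpina1c have values in all 11.

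The effect of the obesogenic diet in offspring of control-fed dams was read from CO against CC. Hepcidin (Hamp, ENSMUSG00000050440), the liver hormone that limits iron export, fell 7.28-fold, from 445.5 ± 26.5 (SD, n = 3) to 60.8 ± 2.97 (SD, n = 2). Of the urea cycle, Asl, argininosuccinate lyase, went from 1428 ± 472 to 313.1 ± 159 (SD, n = 3 and 2). The drug-metabolising cytochrome P450 gene Cyp3a11 (ENSMUSG00000056035) fell from 4587 ± 416 to 854 ± 765. The metalloreductase gene Steap4 rose 10.7-fold, from 60.3 ± 16.5 to 739.9 ± 532. In all, limma called 216 of 12086 genes at an adjusted p under 0.05, of which 122 rose and 94 fell, and 2 of those that fell are the genes listed at 0 in CO. An unadjusted p under 0.05 was met by 2030 genes, with 604 expected by chance.

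Of the urea cycle and amino acid list, 6 of 25 measured members fell (11 adjusted over the list alone) and 0 rose, with Arg1 at 2197 ± 695 in CC and 767.2 ± 35.4 in CO and Hal at 710.0 ± 6.44 and 223.6 ± 90.6. The list median was -0.55 on the log2 scale with an adjusted p of 5.95e-10 by limma's camera and an adjusted p = 0.33 with an estimated correlation. Markers of periportal hepatocytes, of which 9 (Arg1, Hal and Sds among them) are also in the lipid droplet, gluconeogenesis or urea cycle lists, fell in 5 of 15 members (9 adjusted over the list alone), with a median of -1.22. They had an adjusted p of 1.47e-07 by limma's camera and adjusted p = 0.27 with an estimated correlation. Etnppl, an ethanolamine phosphate lyase gene among them, fell by 3.39 on the log2 scale (SE 0.50). Gluconeogenesis genes fell in 3 of 14 members (10 adjusted over the list alone), namely the serine dehydratase Sds, the aspartate transaminase Got1 and the glucose 6-phosphate transporter Slc37a4. By limma's camera their adjusted p was 2.4e-06, and 0.27 as the adjusted p with an estimated correlation. Xenobiotic metabolism genes fell in 4 of 27 members (10 adjusted over the list alone), Cyp3a25, Gstm1, Cyp3a11 and Gsta2, the last with near-identical copies that make its value uncertain. That list had a median of -0.53, an adjusted p of 8.62e-08 by limma's camera and an adjusted p = 0.33 with an estimated correlation. These 4 calls held with each library left out, with medians of -0.88 for the urea cycle and amino acid list and -0.88 for the xenobiotic list without CO.0, and -0.63 for the periportal list without CO.1.

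Acute phase genes were higher, with 3 of 25 members rising (10 adjusted over the list alone) and all 25 members above 0. The 3 were Saa4, the interleukin 1 receptor antagonist Il1rn and the transcription factor Stat3, which went from 102.0 ± 13.2 to 203.4 ± 63.0. The median of 1.49 had an adjusted p of 2.71e-10 by limma's camera, and adjusted p = 0.42 with an estimated correlation. The level of this list, relative to the CC mean, was 3.14 in CO.1 and 0.84 in CO.0. Neutrophil markers rose in 1 of 4 measured members (4 adjusted over the list alone), the calgranulin S100a8, with an adjusted p of 0.000175 by limma's camera and adjusted p = 0.27 with an estimated correlation. Endoplasmic reticulum stress genes were higher with 1 of 23 members past the test (2 adjusted over the list alone), Xbp1, at 177.2 ± 28.8 in CC and 410.1 ± 12.5 in CO. That list had an adjusted p of 1.18e-06 by limma's camera and adjusted p = 0.42 with an estimated correlation. Stellate cell and matrix genes rose in 1 of 18 members (2 adjusted over the list alone), Col4a1, and macrophage markers in 1 of 18 (1 up and 1 down adjusted over the list alone), Mpeg1. Their adjusted p by limma's camera was 8.16e-05 and 0.0176, with adjusted p = 0.33 and adjusted p = 0.56 with an estimated correlation. Pancreas transcripts were higher with a median of 3.73 and 0 of 13 members past the test (0 adjusted over the list alone), at an adjusted p of 0.0015 by limma's camera and adjusted p = 0.56 with an estimated correlation. The pancreas list stood at 6.27 in CO.1 and 0.99 in CO.0. Without CO.1 the pancreas median was 1.02 and the list was no longer called, and it was 6.48 without CO.0, 5.88 without CC.1 and 2.48 without CC.2. The macrophage call ended without CC.0 (0.12), without CO.1 (0.26) and without OC.0 and CO.1 (0.26), but not without OC.1 and CO.1 (0.26). The calls of the other lists held with each library left out, although the acute phase median was 0.53 without CO.1 and 2.30 without CO.0, the neutrophil median of 1.69 was 1.06 without CO.1 and the endoplasmic reticulum stress median of 0.63 was 0.34 without CO.0.

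Limma's camera called 6 more lists. Oxidative phosphorylation genes were lower with a median of -0.28 and 1 of 33 members past the test (2 adjusted over the list alone), Sdhd, and ribosomal protein genes with a median of -0.18 and 0 of 26 (0 adjusted over the list alone). These lists had adjusted p values of 1.88e-09 and 0.000145 by limma's camera, and adjusted p = 0.42 and adjusted p = 0.56 with an estimated correlation. Bile acid genes were lower (median -0.17) with 2 of 24 members past the test (2 up and 7 down adjusted over the list alone), Cyp27a1 and Slco1a4, cholesterol synthesis genes (-0.22) with 1 of 25 (2 adjusted over the list alone), Hsd17b7, and female-biased genes (-0.85) with 0 of 8 (1 up and 3 down adjusted over the list alone). Their adjusted p by limma's camera was 0.0437, 0.049 and 0.0379, with adjusted p = 0.42, adjusted p = 0.68 and adjusted p = 0.42 with an estimated correlation. Male-biased genes were higher (median 0.44) with 0 of 17 members past the test (3 up and 1 down adjusted over the list alone), at an adjusted p of 0.0456 by limma's camera and adjusted p = 0.66 with an estimated correlation. Of these 6 calls, those of oxidative phosphorylation (-0.45 without CO.0, -0.13 without CO.1) and ribosomal protein genes held with each library left out. The male-biased call ended without CO.0 (0.02), CC.0 (0.28) and OO.1 (0.44), with 0.86 without CO.1. Cholesterol synthesis was not called without CO.0 (-0.01), CC.1 (-0.10), OC.0 or OO.1 (-0.22 each), and was called at -0.34 without CC.2, -0.61 without CO.1 and -0.61 without OC.0 and CO.1. Bile acid genes were not called without CC.1 (-0.11) or CO.1 (-0.16), nor female-biased genes without CC.2 (-0.84), OC.0 (-0.85), CO.0 (-0.95) or CO.1 (-1.23).

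Among single genes that rose with values that did not overlap between CO and CC, Moxd1 went from 1.06 ± 1.04 to 173.3 ± 16.6, Serpina4-ps1 from 13.9 ± 5.03 to 175.6 ± 97.4 and the hepatocyte transcription factor Onecut1 from 7.25 ± 5.10 to 58.8 ± 11. Egfros, the transporters Slc37a1, Slc25a30 and Slc41a2, the complement gene C4a and the fatty acid binding protein Fabp5 rose by 6.16-fold to 7.86-fold. C4a and Serpina4-ps1 have close paralogs whose reads may be split. Lower genes included Nipal1 (22.3 ± 7.05 to 2.44 ± 1.80), Cyp2j9 (25.4 ± 2.16 to 4.18 ± 0.258) and Srgap3 (5.32 ± 0.301 to 0.635 ± 0.281). The count fell to 19 without CC.2, 23 without CC.0, 29 without CO.1 and 124 without OC.2, and to 16 without the 2 libraries with pancreas transcripts and 14 without the 2 with high acute phase transcripts. CC.1, which also had pancreas transcripts, stayed in both fits without a pair of libraries. Wherever CO.0 or CO.1 is left out, alone or in a pair, CO is a single library with no spread of its own, and is assumed to vary like the libraries of the other groups. A like count can still hold other genes: without CC.1 limma called 213 genes, of which 147 were among the 216. Many of the 216 also lost their call without CO.0. Of the 18 named genes with values in both groups, Steap4 and Srgap3 kept their call with each library left out, while DESeq2 called 456 genes and voom 104.

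**Figure D2:**
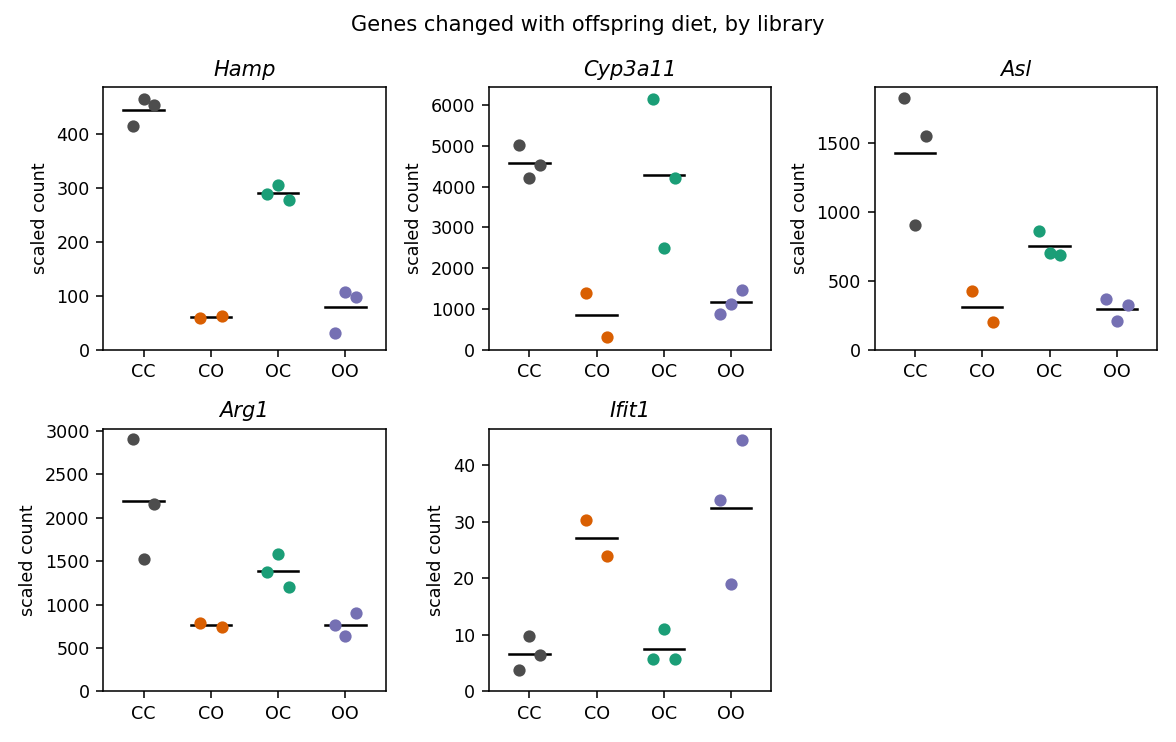
Scaled counts of Hamp, Cyp3a11, Asl, Arg1 and Ifit1 in each library (points), with the group mean as a line. All 5 libraries of obesogenic-fed offspring lie below the 6 of control-fed offspring for Hamp, Cyp3a11, Asl and Arg1, and above them for Ifit1.

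In offspring of obesogenic-fed dams, the obesogenic diet was read from OO against OC. The genes that rose included some that interferon is known to induce. The peptide transporter Tap1 went from 18.4 ± 3.62 to 41.3 ± 5.09 and the RNA editing enzyme Adar from 27.0 ± 0.887 to 46.3 ± 3.77 (SD, n = 3 each). Ifi44, Psmb9, Samd9l, Rnf213 and Trim12c rose by 2.06-fold to 3.01-fold. Hamp fell 4.19-fold, from 291.3 ± 13.5 to 78.8 ± 41.4. Lower too were Srgap3 (7.82 ± 1.03 to 1.12 ± 0.351), the carbonyl reductase Cbr1 (82.9 ± 15.7 to 34.2 ± 6.00), Htatip2 (34.8 ± 4.62 to 15.9 ± 1.48) and the cholesterol synthesis gene Hsd17b7 (89.0 ± 13.9 to 46.9 ± 2.98). Limma called 20 genes, 9 of which rose and 11 fell, and 6 of the 11 are the genes listed at 0.

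Cholesterol synthesis genes were lower in OO than in OC in all 25 measured members, with a median of -0.87, and 1 of them, Hsd17b7, passed over all genes (6 adjusted over the list alone). The list had an adjusted p of 4.53e-14 by limma's camera and adjusted p = 0.45 with an estimated correlation. Its level relative to the CC mean was 1.55 in OC.1 and 0.43 and 0.44 in the other OC libraries, against -0.65 to 0.52 in OO. Gluconeogenesis, urea cycle and amino acid, periportal and xenobiotic genes were lower with medians of -0.44, -0.26, -0.56 and -0.33, and 0 members of each passed over all genes (5 down and 1 up, 2 down, 3 down and 3 down adjusted over the list alone). By limma's camera the adjusted p values were 3.78e-05, 9.25e-05, 4.18e-05 and 1.09e-05, and adjusted p = 0.45, 0.65, 0.45 and 0.45 with an estimated correlation. Ribosomal protein genes were lower by a median of -0.25 (0 adjusted over the list alone) at an adjusted p of 8.06e-12 by limma's camera, and adjusted p = 0.45 with an estimated correlation. Pancreas transcripts were lower (median -2.41, 0 adjusted over the list alone) at an adjusted p of 0.00606 by limma's camera and adjusted p = 0.72 with an estimated correlation, with the list at 6.88 in OC.0 and -0.85 and 1.11 in the other OC libraries. Without OC.0 the pancreas median was 0.05 and limma's camera turned direction, at an adjusted p of 0.984, and without OO.2 (-1.39) the list was not called, with -4.01 without OC.1. Fatty acid oxidation genes were higher (median 0.31, 1 adjusted over the list alone), as were macrophage (0.29, 0 alone), stellate (0.30, 0 alone) and cholangiocyte markers (0.36, 0 alone). In that order their adjusted p by limma's camera was 1.73e-06, 0.0029, 0.00107 and 0.0398, with adjusted p = 0.65, 0.65, 0.45 and 0.45 with an estimated correlation. Within the fatty acid oxidation list the pantetheinase gene Vnn1 stood at 105.4 ± 67.1 in OC and 257.3 ± 22.6 in OO, with an adjusted p of 0.167 by limma. The list call ended for fatty acid oxidation without OC.1 (0.15), urea cycle and amino acid genes without OO.1 (-0.11), macrophage markers without OC.2 (0.16) and stellate markers without OO.2 (0.19). That of cholangiocyte markers ended without OO.2 (0.25), OC.1 (0.27), OC.2 (0.28) or OO.1 (0.39), but not without OC.1 and CO.1 (0.27). Called but moved were cholesterol synthesis (-0.53) and ribosomal protein genes (-0.15) and macrophage markers (0.48) without OC.1, fatty acid oxidation without OC.2 (0.56), macrophage markers without OC.0 (0.18), and xenobiotic (-0.20) and stellate genes (0.46) without OO.0.

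An unadjusted p under 0.05 was met by 968 genes, while edgeR called 23 genes, DESeq2 106 and voom 31. The count was 8 without OC.0 (0 higher), 10 without OC.2 (1 higher), 11 without OO.0 (1 higher), 12 without CC.2 (3 higher) and 13 without OO.2 (2 higher). It was 11 (7 higher) when the 6 genes listed at 0 were not tested. Srgap3 and Htatip2 kept their call with each library left out, and the other 11 named genes did not.

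Averaged over the 2 kinds of dam, the offspring obesogenic diet went with 479 changed genes, 271 higher and 208 lower, 6 of the lower ones being those listed at 0. Hepcidin (Hamp) fell 5.52-fold (SE 0.26 on the log2 scale), Etnppl 5.71-fold, the magnesium transporter gene Nipal1 5.97-fold, the organic anion transporter Slco1a4 5.24-fold, Srgap3 5.20-fold and Cyp3a11 4.94-fold. The chemokine Cxcl1 rose 6.64-fold, from 1.2 ± 0.70 in CC to 30.8 ± 37.7 in CO and from 2.90 ± 1.59 in OC to 15.1 ± 10.3 in OO. Egfros, Onecut1, C4a, Steap4, Slc37a1, Serpina4-ps1, Slc25a30 and the interferon-induced Gbp11 and Ifit1 rose by 4.05-fold to 4.83-fold. Ifit1 stood at 6.67 ± 2.96 in CC, 27.2 ± 4.47 in CO, 7.44 ± 3.04 in OC and 32.5 ± 12.8 in OO. An unadjusted p under 0.05 was met by 2339 genes.

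Of the lists fixed before the data were examined, those of hepatocyte metabolism had the most members changed. In the urea cycle and amino acid list 10 of 25 members fell (13 adjusted over the list alone), with Asl 3.47-fold and Arg1 2.24-fold lower, and in the periportal list 8 of 15 (9 adjusted over the list alone). Gluconeogenesis genes fell in 6 of 14 members (9 down and 1 up adjusted over the list alone), with Got1 2.49-fold lower, and xenobiotic genes in 7 of 27 (9 adjusted over the list alone), with the carboxylesterase Ces2a 2.31-fold lower. Limma's camera gave these 4 lists adjusted p values of 8.03e-09, 2.39e-07, 7.51e-07 and 2.51e-08, and adjusted p = 0.31, 0.28, 0.28 and 0.28 with an estimated correlation. Cholesterol synthesis genes had a median of -0.62 with 2 of 25 members lower (3 adjusted over the list alone), Hsd17b7 and Tm7sf2, ribosomal protein genes -0.20 with 0 of 26 (10 adjusted over the list alone), and oxidative phosphorylation genes -0.13 with 1 of 33 (1 adjusted over the list alone). Their adjusted p by limma's camera was 5.02e-07, 8.03e-09 and 5.11e-06, with adjusted p = 0.49, 0.47 and 0.52 with an estimated correlation. These 3 lists were called with each library left out, at medians of -0.39 for cholesterol synthesis without CO.0 and of -0.23 without CO.0 and -0.06 without CO.1 for oxidative phosphorylation. Without OC.1 and CO.1, the libraries with high acute phase transcripts, oxidative phosphorylation was not called (-0.05). Without OC.0 and CO.1, those with the most pancreas transcripts, the periportal median of -0.91 was -0.57 and that of oxidative phosphorylation -0.08, both called. Female-biased genes were lower as a list of 8, with Fmo2 lower and Rtn4 higher (1 up and 4 down adjusted over the list alone), at an adjusted p of 0.0158 by limma's camera and adjusted p = 0.40 with an estimated correlation.

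Higher lists were acute phase (3 of 25 members, 3 adjusted over the list alone), endoplasmic reticulum stress (2 of 23, Xbp1 and Chac1; 2 up and 1 down adjusted over the list alone) and fatty acid oxidation genes (1 of 33, Vnn1, 3 adjusted over the list alone). Limma's camera gave adjusted p values of 5.51e-06, 0.000468 and 0.0107, and adjusted p = 0.49, 0.52 and 0.68 with an estimated correlation. Of cell type markers, stellate genes had 1 of 18 members higher (6 adjusted over the list alone), Col4a1, neutrophil markers 1 of 4 (3 adjusted over the list alone), S100a8, and cholangiocyte markers 0 of 6 (3 adjusted over the list alone). Macrophage markers had Mpeg1 higher and Trem2 lower among 18 (4 up and 1 down adjusted over the list alone). In that order the adjusted p by limma's camera was 1.61e-05, 0.00158, 0.0492 and 0.0017, with adjusted p = 0.28, 0.28, 0.28 and 0.49 with an estimated correlation. By limma's fry, which asks whether a list moves 1 way on balance, 8 lists passed: gluconeogenesis and periportal (adjusted p 0.021 each), xenobiotic (0.041), urea cycle and amino acid (0.038), and imprinted and fetal, neutrophil, stellate and cholangiocyte genes (0.037 each). The fatty acid oxidation median of 0.15 was 0.08 without CC.1, 0.20 without CO.0 and 0.04 without OC.1, where camera did not call it, and 0.24 without CC.0 or CC.2 and 0.30 without OC.2, where it did. Cholangiocyte markers (0.58) were not called without CC.1 (0.51), OC.1 (0.54), OC.2 (0.54), CC.0 (0.57) or OO.1 (0.60), but were called without OC.1 and CO.1 (0.39). The acute phase median of 0.60 was 0.28 without CO.1, 0.997 without OC.1 and 1.18 without CO.0, each time called, and 0.17 and not called without OC.0 and CO.1. Endoplasmic reticulum stress (0.36) stood at 0.22 without CO.0, and without OC.1 and CO.1 it stood at 0.57, neutrophil markers (0.96) at 0.53 and fatty acid oxidation, not called, at 0.10.

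The remaining 16 lists were not called by limma's camera with the offspring diet, although single members passed. Lipogenesis genes had a median of -0.12 with Mlxipl higher (2 up and 3 down adjusted over the list alone), insulin and glycogen genes -0.01 with Ppp1r3c 3.11-fold lower and Pik3r1 higher (1 and 1), and bile acid genes -0.14 with Cyp27a1, Slco1a4 and Baat among 4 lower and Slco1b2 higher (3 up and 7 down). Male-biased genes had a median of 0.32 with Nudt7 higher (3 up and 1 down adjusted over the list alone). Clock genes had a median of -0.13 with Bhlhe41 higher and Arntl and Cry1 lower (2 and 2 adjusted over the list alone). Immediate early genes had a median of 0.43 with Gadd45b lower, cell cycle genes 0.10 with Rrm2 lower, imprinted and fetal genes 0.23 with Peg3 lower, DNA methylation genes -0.06 with Dnmt3b lower and pericentral genes 0.11 with Slc1a2 higher (adjusted over the list alone 1 down, 1 down, 3 up and 1 down, 1 down and 1 up). Lipid droplet genes (0.09, 2 down adjusted over the list alone), antioxidant genes (-0.05), and erythroid (0.04), endothelial (0.01), adipocyte (0.27) and pancreas transcripts (0.74) had 0 members past the test over all genes. Of these medians, those of the insulin and glycogen, endothelial and pancreas lists changed sign under another scaling, the last to -1.17. The lymphocyte list had only 2 measured members, Cd79b and Ighm, and was not tested by camera.

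**Figure D3:**
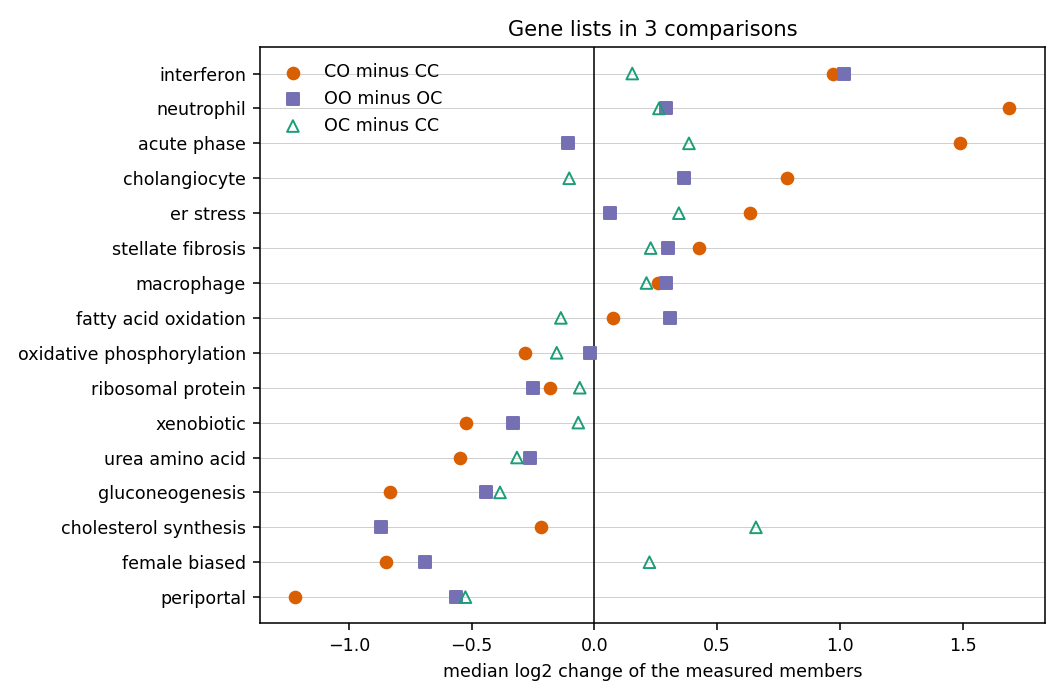
Median log2 change of the measured members of 16 gene lists (y axis) for CO minus CC, OO minus OC and OC minus CC. The interferon list, written after the data were examined, lies at 0.97 and 1.02 in the first and second comparison and at 0.15 in the maternal one, and cholesterol synthesis lies at -0.22, -0.87 and 0.66.

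Fold changes of CO against CC and of OO against OC, which share no library, correlated across genes at Pearson 0.445 and Spearman 0.407, and genes are not independent replicates. Both comparisons called 8 genes higher and 7 lower, with 0.0908 and 0.0856 expected for independent lists. Without the genes listed at 0, 5 were lower in both with 0.0381 expected, and Pearson's value was 0.394. Of the 216 genes called in CO against CC, 209 (96.8%) had the same sign in OO against OC, with a median ratio of 0.446. These genes were selected for their change in CO against CC, and that selection can by itself lower the ratio. The ratio therefore cannot tell whether the diet effect was smaller in offspring of obesogenic-fed dams. In the counts that follow, CC.1, which also had pancreas transcripts, stayed in both fits without a pair of libraries. The count of 479 was 253 without CC.0, 256 without CC.2, 265 without CO.1, 269 without OC.0 and 310 without OO.0, and 134 without the 2 libraries with pancreas transcripts and 250 without the 2 with high acute phase transcripts. Of the 16 named genes with values in all groups, 12 kept their call with each library left out, Hamp, Cyp3a11, Etnppl, Nipal1, Slco1a4, Srgap3, Onecut1, C4a, Steap4, Slc37a1, Ifit1 and Slc25a30, while Cxcl1, Egfros, Gbp11 and Serpina4-ps1 did not.

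The maternal diet alone was read from OC against CC, in offspring fed the control diet. Cholesterol synthesis genes were higher in OC in all 25 measured members, with a median of 0.66: Hmgcs1, the HMG-CoA synthase gene, stood at 138.1 ± 23.6 in CC and 349.6 ± 153 in OC, and Cyp51 at 50.4 ± 21.6 and 120.4 ± 70.2 (SD, n = 3 each). For this list limma's camera gave an adjusted p of 5.08e-12, and adjusted p = 0.59 with an estimated correlation, and 0 single members passed (0 adjusted over the list alone). Its level was 1.55 in OC.1, 0.43 in OC.0, 0.44 in OC.2 and 0.38 in CC.1, so that 1 CC library came close to 2 of the OC libraries. OC.1 is also the OC library with high acute phase transcripts. Without it the median was 0.35, and limma's camera still called the list.

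Other lists called by limma's camera in OC against CC were lower for urea cycle and amino acid (median -0.32), oxidative phosphorylation (-0.15), gluconeogenesis (-0.39), periportal (-0.53), fatty acid oxidation (-0.14) and ribosomal protein genes (-0.06). By limma's camera adjusted p values were 9.09e-08, 2.28e-08, 7.19e-05, 0.000125, 0.0273 and 0.0206, with adjusted p = 0.59, 0.73, 0.59, 0.59, 0.94 and 0.94 with an estimated correlation. Endoplasmic reticulum stress (0.34), macrophage (0.21), stellate (0.23), acute phase (0.39) and pancreas transcripts (2.50) were higher, with adjusted p values of 5.56e-05, 0.00115, 0.000814, 0.00602 and 0.00133 by limma's camera, and adjusted p = 0.73, 0.73, 0.59, 0.94 and 0.94 with an estimated correlation. In each of these lists 0 members passed, over all genes and adjusted over the list alone. The fatty acid oxidation and acute phase medians were -0.01 and -0.04 without OC.1, the ribosomal protein median was 0.01 without OC.0, and limma's camera turned direction in each case. The pancreas median was 0.14 without OC.0, 1.43 without CC.0 and 1.299 without CC.2, each time without a call, and 3.99 without OC.1 and 4.63 without CC.1. Not called without OC.1 were endoplasmic reticulum stress (0.10), macrophage (0.07) and stellate genes (0.13), and without CC.0 endoplasmic reticulum stress (0.08) and macrophage genes (0.06). Fatty acid oxidation was not called without CC.2 (-0.02) or OC.0 (-0.03), nor ribosomal protein without CC.1 (-0.07), CC.2 (-0.05) or OC.2 (-0.06). Thus 5 of the 12 lists were called with each library left out: cholesterol synthesis, gluconeogenesis, oxidative phosphorylation (-0.10 without OC.0), urea cycle and amino acid, and periportal genes (-0.33 without OC.1, -0.31 without OC.2). Other calls that held at moved medians were fatty acid oxidation without CC.1 (-0.25) and OC.2 (-0.32), acute phase without OC.0 (0.65) and OC.2 (0.73), ribosomal protein without OC.1 (-0.17) and macrophage without OC.2 (0.34).

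No single gene passed in OC against CC: limma called 0 of 12086 genes with a lowest adjusted p of 0.923, 636 genes had an unadjusted p under 0.05 against 604 expected, and edgeR, DESeq2 and voom called 0 each. The 5 genes closest to the threshold in each direction among those whose values did not overlap were Sp140, Pfkl, Col27a1, Tsku and Aox1 higher and Retreg1, Heatr1, Zbed5, Klhdc2 and Rps4l lower, all missing it. Retreg1, a receptor for autophagy of the endoplasmic reticulum, had the lowest unadjusted p of them, at 130.0 ± 18.9 in CC and 77.4 ± 2.38 in OC with an adjusted p of 0.923 by limma. Without CC.1, limma called 2 genes.

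In offspring fed the obesogenic diet, the maternal diet was read from OO against CO. Gas1, a growth arrest protein gene, rose from 3.50 ± 0.00543 (SD, n = 2) to 8.80 ± 1.03 (SD, n = 3), with an adjusted p of 0.0112 by limma, and stood at 12.5 ± 0.111 in CC and 11.6 ± 0.418 in OC. It was the only gene of the 5 called that had values in both groups, since the other 4 were the genes listed at 0 in OO. Genes that missed the threshold included Zfp467, Kctd2, Hist1h4h, Ppp1r3c and Tdp2 on the higher side and Wdr45b, Steap4, Xbp1 and Ptp4a1 on the lower side. Acute phase genes were lower in OO in all 25 members, with a median of -0.95, an adjusted p of 4.35e-12 by limma's camera and adjusted p = 0.63 with an estimated correlation, with CO.1 at a level of 3.14. Without CO.1, and without OC.0 and CO.1, the median was -0.21 and limma's camera did not call the list (adjusted p 0.138 and 0.14), while without OC.1 and CO.1 it was also -0.21 and called (adjusted p 0.01). Without CO.0 it was -1.67.

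Lists lower in OO than in CO were also neutrophil (median -0.92, 2 adjusted over the list alone), male-biased (-0.60, 0 alone), endoplasmic reticulum stress (-0.23, 1 alone), ribosomal protein (-0.12, 0 alone), erythroid (-0.78, 0 alone) and pancreas transcripts (-3.54, 0 alone). Limma's camera gave adjusted p values of 0.000998, 0.00262, 0.00262, 0.000731, 0.0163 and 5.81e-05, with adjusted p = 0.63 for each with an estimated correlation. Lipogenesis (0.23, 1 adjusted over the list alone, Srebf1), lipid droplet (0.23, 0 alone), fatty acid oxidation (0.14, 0 alone), xenobiotic (0.37, 0 alone), oxidative phosphorylation (0.11, 0 alone) and macrophage genes (0.18, 0 alone) were higher. Their adjusted p by limma's camera was 0.00507, 0.0285, 0.0475, 0.00194, 0.0034 and 0.0294, with adjusted p = 0.63, 0.63, 0.77, 0.63, 0.68 and 0.63 with an estimated correlation. Without CO.1 the test of the xenobiotic and oxidative phosphorylation lists turned direction, with medians of 0.15 and -0.08. Each of the 13 lists called in OO against CO, acute phase included, lost its call or turned without at least 1 library. Without CO.0 the calls ended for male-biased (-0.07), erythroid (-0.02), endoplasmic reticulum stress (-0.05), ribosomal protein (-0.07), lipogenesis (0.18), lipid droplet (0.31), fatty acid oxidation (0.17) and macrophage genes (0.07). Without CO.1 they ended for pancreas (-0.83), neutrophil (-0.37) and fatty acid oxidation genes (0.03). Leaving out OO.2 ended them for male-biased (-0.22), endoplasmic reticulum stress (-0.11), lipogenesis (0.05), lipid droplet (0.10), xenobiotic (0.18) and oxidative phosphorylation genes (0.07). Erythroid genes were not called without OO.0 (-0.70) or OO.1 (-0.62), macrophage genes without OO.1 (0.11) or without OC.0 and CO.1 (0.18), nor fatty acid oxidation without OO.0 (0.07), OO.1 (0.15) or OC.0 (0.14). Called at moved medians were pancreas (-6.14), neutrophil (-1.48), xenobiotic (0.73) and oxidative phosphorylation (0.26) without CO.0, erythroid (-1.60) and endoplasmic reticulum stress (-0.41) without CO.1, endoplasmic reticulum stress (-0.45) and oxidative phosphorylation (0.16) without OO.1, and lipogenesis (0.35) without OO.0.

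An unadjusted p under 0.05 was met by 715 genes, edgeR and voom called 5 each and DESeq2 16, and limma called 20 without CO.0. Gas1 lost its call when the 6 genes listed at 0 were not tested, leaving 0 genes by limma, and also without CO.1, OO.1 or OO.2 (highest adjusted p 0.118 by limma).

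Averaged over the offspring diets, the maternal obesogenic diet went with higher cholesterol synthesis genes, in all 25 members and with a median of 0.43, and with higher macrophage markers, in all 18 members and with a median of 0.20. Limma's camera gave adjusted p values of 1.92e-07 and 0.000424, and adjusted p = 0.58 for both with an estimated correlation. The cholesterol synthesis average came mostly from OC against CC (0.66), since in OO against CO the list had a median of 0.18 with 17 of 25 members above 0 and was not called, at an adjusted p of 0.208 by limma's camera. Lipogenesis (0.19), stellate (0.15) and xenobiotic genes (0.14) were higher, and ribosomal protein (-0.09), acute phase (-0.37), gluconeogenesis (-0.12), urea cycle and amino acid (-0.10), male-biased (-0.29) and erythroid genes (-0.50) were lower. Their adjusted p by limma's camera was 0.019, 0.019, 0.0369, 7.96e-05, 0.00181, 0.0091, 0.019, 0.019 and 0.0295, with adjusted p = 0.58 for each with an estimated correlation. In these 11 lists 0 members passed, over all genes and adjusted over the list alone. The test of the acute phase list turned direction without CO.1 (median 0.08) and so did that of the xenobiotic list (0.07), while the urea cycle and amino acid list turned without CO.0 (0.06). With each library left out, limma's camera kept 3 of the 11 calls, those of cholesterol synthesis (0.25 without OC.1), macrophage (0.12 without CC.0) and ribosomal protein genes (-0.14 without CO.1, -0.05 without OC.0, -0.15 without OC.1). Without CO.0 it did not call male-biased (0.01), erythroid (-0.10), lipogenesis (0.16) or stellate genes (0.11). Without CC.1 it did not call male-biased (-0.24), erythroid (-0.49), lipogenesis (0.18), stellate (0.19) or xenobiotic genes (0.10). Male-biased genes were also not called without OC.0 (-0.20) or OO.2 (-0.14), and erythroid genes without OC.0 (-0.34), OC.2 (-0.42), OO.0 (-0.42) or OO.1 (-0.36). Lipogenesis was not called without OC.2 (0.19) or OO.2 (0.09), stellate genes without OC.1 (0.13) or OO.2 (0.12), and xenobiotic genes without CC.2 (0.16), OC.0 (0.15), OC.1 (0.19), OC.2 (0.13) or OO.2 (0.08). Gluconeogenesis was not called without OO.1 (-0.09), urea cycle and amino acid genes without CC.0 (-0.08), OC.2 (-0.09) or OO.1 (-0.01), nor acute phase without OC.2 (-0.12). Called at moved medians were male-biased without CC.0 (-0.59), CO.1 (-0.53), OC.1 (-0.54) and OO.0 (-0.50), erythroid without CO.1 (-0.91), and acute phase without CO.0 (-0.68), OC.0 (-0.24) and OC.1 (-0.62). So were gluconeogenesis without OC.0 (-0.19) and OO.0 (-0.23), urea cycle and amino acid without CO.1 (-0.26) and OO.2 (-0.18), and xenobiotic genes without CO.0 (0.35). Without OC.0 and CO.1 cholesterol synthesis stood at 0.68, urea cycle and amino acid genes at -0.29, male-biased genes at -0.38 and erythroid genes at -0.73, all called. Without OC.1 and CO.1 stellate genes were not called (0.14), and called were acute phase (-0.19), ribosomal protein (-0.19), macrophage (0.12), urea cycle and amino acid (-0.27), male-biased (-0.61) and erythroid genes (-1.08).

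The 4 genes that limma called for the maternal average, all lower, were Serpina1b, Serpina1d, Gm8893 and Gm24105, which are listed at 0 in OO. Without the genes listed at 0 limma called 0 genes with 741 at an unadjusted p under 0.05 in the full test, while on all genes edgeR and voom called 4 each and DESeq2 8. Genes that missed the threshold included Plscr1, Retreg1, Eif4ebp3 and Heatr1 on the lower side and Hist1h4h, Csad, Aox1, Sned1 and Sparcl1 on the higher side. Csad, which makes hypotaurine from cysteine sulfinate, stood at 364.2 ± 66.6 in CC, 667.5 ± 62.9 in OC, 100.4 ± 4.62 in CO and 227.9 ± 135 in OO, with an adjusted p of 0.789 by limma. Fold changes of OC against CC and of OO against CO correlated across genes at Pearson -0.114 and Spearman 0.059, and genes are not independent replicates. Pearson's value ranged from -0.199 without OO.1 to 0.011 without CO.1, and was -0.031 without OC.0.

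Whether the offspring diet acted differently by dam was asked with the interaction, the change of OO against OC less that of CO against CC. Acute phase genes had a lower change in offspring of obesogenic-fed dams in all 25 members, with a median of -1.48, and endoplasmic reticulum stress genes in all 23, with a median of -0.56. Urea cycle and amino acid genes, whose change was less negative there, had a positive term in all 25 members (median 0.46), and oxidative phosphorylation genes in all 33 (median 0.27). Limma's camera gave these 4 lists adjusted p values of 3.67e-13, 1.02e-07, 1.03e-05 and 8.69e-10, with adjusted p = 0.61 for each with an estimated correlation and 0 members past the test in each (0 adjusted over the list alone). The acute phase median was -0.56 without CO.1 and -0.79 without OC.1, and without both it was -0.01 and limma's camera no longer called the list. Urea cycle and amino acid genes were not called without CO.1 (0.13), without OC.1 and CO.1 (0.10) or without OC.0 and CO.1 (0.19). Oxidative phosphorylation, at 0.43 without CO.0 and 0.10 without CO.1, lost its call without OC.1 and CO.1 (0.10) and without OC.0 and CO.1 (0.04). Endoplasmic reticulum stress was called throughout, at -0.37 without CC.0, -0.36 without OC.1 and -0.90 without OC.0 and CO.1. Among single genes, Gas1 came closest, with values of 12.5 ± 0.111 in CC, 3.50 ± 0.00543 in CO, 11.6 ± 0.418 in OC and 8.80 ± 1.03 in OO, and missed the threshold at an adjusted p of 0.0842 by limma.

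Limma called 4 genes for the interaction, the 4 listed at 0 in OO alone, and 0 without them. An unadjusted p under 0.05 was met by 551 genes against 604 expected, and on all genes edgeR and voom called 4 each and DESeq2 6. Of the 6 genes called by DESeq2, only 2 were among the 4 called by limma. Other genes that missed the threshold were Zfp467, Sfxn1, Manbal and Gpihbp1 with a positive term and P4ha2, Steap4, Wdr45b, Cldn14 and Xbp1 with a negative one. The CO group had 2 libraries, of which CO.1 carried the pancreas and acute phase transcripts. Without CO.1 limma's camera called 7 lists for the interaction in place of 13, and not all of the 7 were among the 13.

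**Figure D4:**
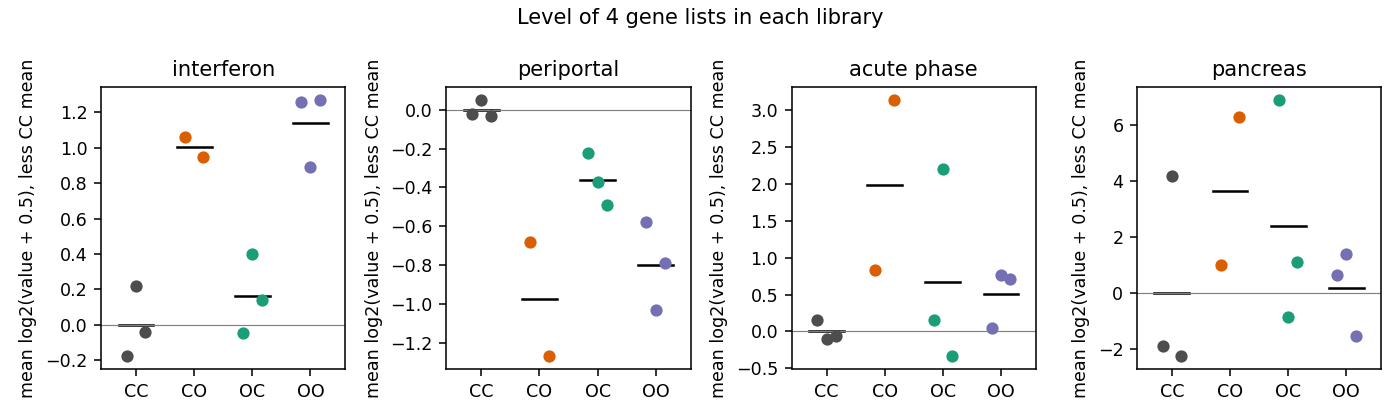
Mean log2(value + 0.5) of 4 gene lists in each library (points), less the CC mean, with the group mean as a line. The interferon list is at 0.89 to 1.27 in the 5 libraries of obesogenic-fed offspring and at -0.18 to 0.40 in the other 6, the acute phase list is highest in CO.1 (3.14) and OC.1 (2.20), and the pancreas list in OC.0 (6.88) and CO.1 (6.27).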

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

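The tests of explanations for the genes listed at 0, and the fits without pairs of libraries, were chosen only after the results were seen. The interaction and the fits without single libraries were planned.

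The interaction in limma called only 4 genes, those listed at 0 in OO alone: Serpina1b (adjusted p 1.36e-12), Serpina1d (2.89e-11), Gm24105 (6.94e-08) and Gm8893 (0.00198). These values follow from the exact 0 in every OO library, which can be a failed estimate. They therefore cannot show that the offspring diet acted differently by dam. With limma's camera the interaction also called 13 lists. Medians were negative for acute phase (-1.48), neutrophil (-1.35), male-biased (-0.69), endoplasmic reticulum stress (-0.56), cholesterol synthesis (-0.42) and pancreas genes (-6.09). They were positive for periportal (0.55), urea cycle and amino acid (0.46), gluconeogenesis (0.38), lipid droplet (0.28), fatty acid oxidation (0.28), oxidative phosphorylation (0.27) and xenobiotic genes (0.26). Camera with an estimated correlation gave an adjusted p of 0.61 for each of the 13 in limma, and camera called 4 lists without OC.1 and CO.1, 7 without OC.0 and CO.1 and 7 without CO.1. In each of those fits at least 1 list called was not among the 13. The xenobiotic list turned direction without CO.1 (median -0.068) and without OC.1 and CO.1 (-0.047), and so did the cholesterol synthesis list without OC.1 and CO.1 (0.041). The pancreas median was -3.26 without CO.1 and -3.80 without OC.0, and without both it was -1.03 and the list was not called. That of acute phase was -0.56 without CO.1 and -0.79 without OC.1, and without both it was -0.01 and the list was not called. Oxidative phosphorylation was 0.43 without CO.0 and 0.10 without CO.1, and not called without OC.1 and CO.1 (0.10) or OC.0 and CO.1 (0.04), while endoplasmic reticulum stress was called in all of these, at -0.37 without CC.0, -0.36 without OC.1 and -0.90 without OC.0 and CO.1. The other 9 lists lost their call or turned without at least 1 library. Without CO.1 neutrophil (-0.79), periportal (0.43), urea cycle and amino acid (0.13), gluconeogenesis (0.39), fatty acid oxidation (0.19) and cholesterol synthesis genes (-0.26) were not called. Male-biased genes were not called without CO.0 (-0.14), OO.2 (-0.28), CC.0 (-0.44), OC.1 (-0.47) or OO.1 (-0.64), nor cholesterol synthesis without OC.1 (-0.08), fatty acid oxidation without CC.2 (0.16) or OC.1 (0.12), or xenobiotic genes without OO.2 (0.10). Gluconeogenesis was not called without OO.0 (0.21), CC.0 (0.34), CO.0 (0.34) or CC.2 (0.38), nor lipid droplet genes without OC.1 (0.20), CC.2 (0.22), OO.2 (0.24), CC.0 (0.28) or CO.0 (0.42). Called at moved medians were cholesterol synthesis without CO.0 (-0.85), OO.0 (-0.21) and OO.2 (-0.68), lipid droplet without CC.1 (0.46), OC.2 (0.43) and OO.0 (0.45), and xenobiotic genes without CO.0 (0.63) and OO.0 (0.44). Without OC.1 and CO.1, further lists not called were neutrophil (-0.81), periportal (0.31), urea cycle and amino acid (0.10), gluconeogenesis (0.35), lipid droplet (0.38) and fatty acid oxidation (0.06), and male-biased genes were called (-0.75). Without OC.0 and CO.1, those not called were neutrophil (-0.72), periportal (0.37), urea cycle and amino acid (0.19), gluconeogenesis (0.32), fatty acid oxidation (0.16) and xenobiotic genes (0.08), and called were acute phase (-0.84), cholesterol synthesis (-0.36) and male-biased genes (-1.17).

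Among all genes and groups, 0 pairs of a gene at 100 or more and a group had only part of the libraries at 0, against 6 pairs with all of them, from mt-Rnr2, Mup17, Serpina1b and Serpina1d, which is consistent with values set to 0 for whole groups before deposit, while Gm8893 and Gm24105 lie under 100 and are not covered. Reads of Serpina1b and Serpina1d moved to near-identical copies are argued against, which leaves Mup17 open, since the 5 Serpina1 genes together reached only 35.9% of their OC level in OO (2289 to 3694 against 7199 to 10470). A loss of mitochondrial rRNA is argued against by mt-Rnr1, at a log2 change of 0.281 (SE 0.235) with the offspring diet. A true loss of Serpina1b and Serpina1d in the OO animals cannot be told apart from a processing step, because both leave no reads, where 68530 Serpina1b reads would be in OO.0 at the OC mean.

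The 10 splits of the libraries are too few to judge the simple comparisons. The real counts and the highest of the other splits were 216 and 2 for CO with CC, 20 and 0 for OO with OC, 0 and 1 for OC with CC, and 5 and 3 for OO with CO. Without the genes listed at 0 they were 214 and 2, 11 and 0, 0 and 1, and 0 and 3. For the offspring diet average 1 of 100 splits, the real one, gave as many genes (479 against 82 at most in the others, and 473 against 76 without the genes listed at 0). This argues against a chance division of these libraries. Which libraries share a litter is not known, so chance differences between litters are not covered. For the maternal average 8 of 100 splits gave 4 genes or more, with up to 13, so chance is not excluded. For the interaction 5 of 100 did so, with up to 21. Those splits shuffled all 11 libraries over the 4 groups and so also moved the offspring diet difference. They cannot judge the interaction, for which chance stays open. Without the genes listed at 0 the real count was 0 in both, which any split must reach, and the other splits gave up to 13 and 22. Splits calling several times the real count may reflect a structure of the libraries, but what gave those calls was not tested.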

How the results depend on the processing

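Fits without genes listed at 0, without the pair of libraries with the most pancreas transcripts and without the pair with high acute phase transcripts were chosen only after the results were seen. CC.1, which also had pancreas transcripts, was kept in each of them. No paired analysis was possible because the columns carry no replicate numbers of the labels. The filter at a value of 1 removed no gene, so its comparison with no filter is void. Of named genes, 988 of the refits with 1 library left out kept the side of the threshold, 153 lost the call and 3 gained it, and of other alternatives 1373, 108 and 11. These refits include genes listed at 0 and named genes that missed the threshold, which keep their side by staying uncalled. The calls lost with 1 library left out were mostly in CO against CC (68) and OO against OC (66). For called lists 868 kept the call, 123 lost it and 10 turned direction with 1 library left out, and 747, 55 and 13 otherwise. Without CO.0, without CO.1 and without either pair, CO is 1 library, assumed to vary like those of the other groups. Depth limits low genes, as 3 reads are worth up to 0.829 in OO.1. Except where stated, the cause was not tested.

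For CO against CC (216 genes by limma) DESeq2 called 456, voom 104, the 2 groups alone 92, an adjusted p under 0.1 gave 472 and a log2 change of at least 1 gave 132. Without the acute phase pair 14 were called and without the pancreas pair 16, with fewer libraries. With 1 library left out the count ran from 19 (CC.2) to 233 (OO.2), with 23 without CC.0, 29 without CO.1 and 124 without OC.2. For OO against OC (20) DESeq2 called 106, voom 31, the 2 groups alone 12, sample weights 124, the fit without genes listed at 0 gave 11, without the acute phase pair 35 and without the pancreas pair 12, and leaving out 1 library gave 8 (OC.0) to 30 (CO.1), with 10 without OC.2, 11 without OO.0, 12 without CC.2 and 13 without OO.2. For OC against CC limma called 0 (636 at an unadjusted p under 0.05, and 0 by edgeR, DESeq2 and voom) and 0 to 2 with 1 library left out (2 without CC.1). For OO against CO (5) DESeq2 called 16, and limma called 0 without genes listed at 0 (715 at an unadjusted p under 0.05 on all genes, where edgeR and voom called 5) and 4 to 20 with 1 library left out (20 without CO.0).

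For the offspring average (479) DESeq2 called 770, sample weights 747, the fit without the acute phase pair 250, without the pancreas pair 134, an adjusted p under 0.1 gave 916 and a log2 change of at least 1 gave 160. Leaving out 1 library gave 253 (CC.0) to 483 (CC.1), with 256 without CC.2, 265 without CO.1, 269 without OC.0 and 310 without OO.0. For the maternal average (4) DESeq2 called 8, limma 0 without genes listed at 0 (741 at an unadjusted p under 0.05 on all genes, where edgeR and voom called 4) and 3 to 6 with 1 library left out. For the interaction (4) limma called 0 without genes listed at 0 (551 at an unadjusted p under 0.05 on all genes, where edgeR and voom called 4 and DESeq2 6) and 4 to 5 with 1 library left out. DESeq2 shared 2 of its 6 genes with limma.

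Lists called by limma's camera numbered 16, 11, 12, 13, 15, 11 and 13 for the comparisons in that order, 0 in each with an estimated correlation, and 3, 0, 0, 0, 8, 0 and 0 by fry. With 1 library left out they were 13 to 17, 10 to 12, 8 to 12, 7 (OO.2) to 16, 13 to 18, 6 (CC.1; 7 without OO.2) to 12 and 7 (CO.1) to 16. Without the pancreas pair OO against CO had 7 and the interaction 7, and without the acute phase pair the interaction had 4. Such counts can include lists that were not called with all libraries. The correlation of offspring diet effects ran from 0.336 to 0.494 with 1 library left out, and that of maternal effects (-0.114) from -0.199 (OO.1) to 0.011 (CO.1), with -0.031 without OC.0, 0.049 without the acute phase pair and -0.031 without the pancreas pair.

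Camera turned direction in these lists, given with their medians and, in brackets, the lowest and highest with 1 library left out. In OO against OC pancreas genes had 0.046 without OC.0 and without the pancreas pair (-4.011 to 0.046). In OC against CC fatty acid oxidation had -0.005 (-0.321 to -0.005) and acute phase -0.035 (-0.035 to 0.730) without OC.1 and without the acute phase pair, and ribosomal protein 0.010 without OC.0 and without the pancreas pair (-0.168 to 0.010). In OO against CO xenobiotic genes had 0.146 (0.146 to 0.732) and oxidative phosphorylation -0.078 (-0.078 to 0.257) without CO.1 and without either pair. In the maternal average xenobiotic genes had 0.072 without CO.1, 0.093 without the acute phase pair and 0.073 without the pancreas pair (0.072 to 0.349), urea cycle and amino acid genes 0.055 without CO.0 (-0.256 to 0.055), and acute phase 0.083 without CO.1 and 0.117 without the pancreas pair (-0.683 to 0.083). In the interaction cholesterol synthesis had 0.041 without the acute phase pair, and xenobiotic genes -0.068 without CO.1 and -0.047 without the acute phase pair (-0.068 to 0.627).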

Other observations

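The tests on interferon, macrophage, pancreas and muscle transcripts below were all chosen only after the results were seen, and the interferon and muscle lists were written then.

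Interferon-stimulated genes were higher with the offspring obesogenic diet for both kinds of dam. Of 49 measured genes, 40 rose in the offspring diet average by limma (47 adjusted over the list alone) and 0 fell, with a median log2 change of 1.01. In CO against CC 21 rose (42 adjusted over the list alone, median 0.97) and in OO against OC 7 (46 adjusted over the list alone, median 1.02). The list includes genes already seen to rise, such as Tap1, Rnf213 and Adar, and so is not independent evidence. Limma's camera with an estimated correlation gave an unadjusted p = 0.0042 for the average, 0.01 for CO against CC and 0.0024 for OO against OC. With the maternal diet 0 of 49 passed in OC against CC (median 0.15) by limma.

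More macrophages could raise interferon-stimulated genes. The interferon list, which shares 0 genes with the macrophage list, exceeded the macrophage list by 0.77 on the log2 scale (SE 0.13, 95% interval 0.47 to 1.07). However, the interferon list was written after these libraries were seen and holds genes already seen to rise. Its excess was therefore favoured and does not decide whether more macrophages account for the rise. The libraries with pancreas or high acute phase transcripts are argued against as the source, since the median was 0.99 without the former pair and 1.10 without the latter, and 0.94 to 1.09 with any 1 library left out. Splits of the libraries decide nothing here, since the list was written after these libraries were seen (median 1.01, and 0.92 at most in the other splits of 100). An effect of the offspring diet on interferon signalling stays a hypothesis, found and tested on the same libraries.

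Exocrine pancreas transcripts made up 0.701% of values in OC.0, 0.418% in CO.1 and 0.0971% in CC.1, with Ctrb1 at 753.9 and 535.7 and Cela2a at 706.2 and 454.9 in OC.0 and CO.1. None of the 13 genes is in another list. Pancreas tissue taken with the liver piece may account for them, but this was not told apart from other sources. All 13 genes were above the median of all libraries in OC.0 and CO.1, but these libraries were picked for high values. Their log2 values correlated at 0.97 between these libraries across genes, which are not independent replicates. A shared rise from another source could give the same correlation. A change with either diet averaged over the other would not account for the differences within a group, where the level ranged by up to 7.73 on the log2 scale. The diets differed by 0.70 (offspring) and 0.54 (maternal). With such a spread within groups, a diet difference of that size can be neither seen nor excluded. A change with one diet that depends on the other stays open, because the groups differed by 3.63 (CO less CC), -2.22 (OO less OC), 2.38 (OC less CC) and -3.47 (OO less CO), and the range within a group was only 1.32 times the interaction of -5.85.

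Skeletal muscle transcripts, 14 genes measured, had a median log2 change of -0.18 with the offspring diet (0.57 under another scaling) and 0 genes past the test by limma, with levels of 2.93 in OO.0, 1.76 in CC.0 and 1.47 in CO.1 relative to the CC mean. Lars2 stood at 142071 in OO.1 and 337 to 10220 in the other libraries, and Gm15564 at 15970 in OO.1.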
